A study of Mus musculus with 12 samples.

How the data were processed

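MTEC1 cells, a mouse line that the labels describe as medullary thymic epithelial, were treated with PAMK or left untreated. PAMK is the usual abbreviation for a polysaccharide from the rhizome of Atractylodes macrocephala Koidz. The labels give a dose of 50 µg/ml for 12 h, and the series design gives 6 h for the control cultures, so treatment and culture time differ together if that text is right. Each of 4 groups had 3 libraries: total RNA control, total RNA PAMK, small RNA control and small RNA PAMK. Nothing in the labels says whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

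For total RNA, ribosomal RNA was removed and paired reads were made on a NovaSeq instrument, per the labels' protocols. The submitters' processing notes name cutadapt, FastQC, HISAT2, StringTie and edgeR. Versions, genome build, annotation and strand setting are not given in the sources used here. The deposited mRNA and lncRNA values were taken as FPKM, although the file headers call them normalized counts: the layout is that of StringTie output, and the columns do not share a total. This unit is inferred, and a fragment count behind each value was not recovered, so the depth of the total RNA libraries is unknown. A deposited value of 0.0001 FPKM stands for nothing measured and filled 57.2% to 58.1% of mRNA transcripts per control library, 55.6% to 56.3% per PAMK library and 38.6% to 40.1% of lncRNA transcripts per library. The deposited FPKM summed to between 133684 and 145879 per library in the mRNA table and to between 79925 and 88531 in the lncRNA table. Gene positions are printed as deposited, with a build not given in the sources used here. Of 21198 gene symbols also present in a RefSeq table for GRCm38.p6, 21195 overlapped the gene of that name by position.

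For small RNA, TruSeq small RNA libraries were read on a HiSeq instrument, and the ACGT101-miR program removed adapter dimers, common RNA families and repeats, per the labels' protocols. The deposited small RNA signal is called normalized counts in the file headers; how it was normalized is not given in the sources used here. The values of a library lie largely on multiples of 1 step, as reads divided by a library factor would: 88.6% to 94.4% of values under 200 steps were whole within 0.02. That share was too low to treat the values as counts, so no count test was run. Dividing by the step gives an estimated 4104360 (PAMK 1) to 6791570 (PAMK 3) reads per library. Only 7 to 17 values per library lay below 5 steps, against 39 to 52 at 5 steps, so a 0 may stand for a few reads.

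Transcript FPKM were summed by gene name for the gene comparison, with the placeholder set to 0. Genes and mRNA transcripts with a mean of at least 0.5 FPKM over the 6 libraries were tested on log2(FPKM + 1), lncRNA transcripts with a mean of at least 0.1 on log2(FPKM + 0.1), and small RNAs with a mean of at least 10 normalized counts on log2(value + 1). Fold changes are on these scales and understate the change of low genes. The test was limma 3.58.1 in R 4.3.3 with an intensity trend, two-sided, with Benjamini-Hochberg adjustment at 0.05. Lists of genes were written before the data were examined. The 22 of 27 mRNA lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Sums of lncRNA transcripts by gene name, used for the lncRNA lists, were chosen after the data were seen.

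Genes were named by a rule set before the data were examined. It took up to 12 mRNA genes with the largest rise and 12 with the largest fall among those past the threshold, with no overlap between groups and a mean of at least 1 FPKM in a group, leaving out predicted and clone names. For lncRNAs (at least 0.5 FPKM) and small RNAs (at least 10) it took up to 6 each way. Where fewer than 6 mRNA genes or 3 of the others passed in a direction, the smallest p filled that number. From each list up to 4 members with the smallest p could be named, and Krt5, Krt8, Krt18, Epcam, Aire, Mki67, Pcna, Ccnd1, Myc, Cdkn1a, Tlr4, Il7, Malat1, Neat1 and miR-21a-5p were always named.

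The steps were tested on simulated data with the real means and spreads, in which 100 of the tested genes or RNAs changed 2-fold and 100 changed 8-fold. Of 9781 mRNA genes, 56% of the 2-fold and 71% of the 8-fold changes were called, with 8 false calls. Of 14729 mRNA transcripts, 17% and 65% were called, with 4 false calls. Of 23670 lncRNA transcripts, 0% and 47% were called, with 3 false calls. Of 479 small RNAs, 81% and 98% were called, with 4 false calls. With nothing changed, each of the 4 simulations gave 0 calls. The simulated noise was normal and independent between rows, without transcripts that drop to the placeholder. The folds were set on the tested log2 scale, pseudocount included, so in low rows they stand for larger changes in FPKM. A simulated fall of a low row can also go below 0 FPKM, which real values cannot. The rates are therefore not those for 2-fold and 8-fold changes in the FPKM of low rows. Other divisions of the 6 real total RNA libraries called 3 to 17 genes, 4 to 25 transcripts and 0 to 16 lncRNAs. The 0 calls therefore do not show how many false calls the real values give. The rates hold for 200 changed rows, where the adjustment is less strict than with few changes. Alternatives were another pseudocount, filter, scaling and variance model, leaving out each library, the replicate number as a block, and those added after the data were seen, which the closing section names.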

Results

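Gene expression was measured in MTEC1 cells with and without PAMK in 6 total RNA libraries and 6 small RNA libraries, 3 per group. There were 59215 mRNA transcripts of 21771 genes, 42870 lncRNA transcripts and 845 small RNA entries. Control libraries were similar at the level of small RNAs (Pearson r of log2 values 0.981 to 0.993) and less so at the level of genes (0.881 to 0.887) and lncRNA transcripts (0.729 to 0.745). For genes, correlations between PAMK and control libraries (0.880 to 0.891) overlapped those within the PAMK group (0.886 to 0.894).

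The first comparison asked which mRNA genes differed between PAMK and control cells. Ranbp10 fell from 8.98 ± 0.346 to 0.0664 ± 0.00945 FPKM (SD, n = 3). Nfe2l1, a transcription factor that controls proteasome genes, fell from 20.8 ± 2.20 to 2.13 ± 0.0898 FPKM, and Ilvbl fell from 17.5 ± 2.56 to 2.00 ± 0.382 FPKM. Glrx, the glutathione-dependent redox enzyme glutaredoxin, fell from 13.6 ± 2.23 to 0.413 ± 0.463 FPKM. Rbm4, an RNA-binding splicing regulator, rose from 0.761 ± 0.0911 to 5.64 ± 0.325 FPKM, and Mrpl15, a protein of the mitochondrial ribosome, rose from 7.04 ± 0.356 to 13.9 ± 0.221 FPKM. Most of each rise lay in 1 transcript. Rbm4 transcript ENSMUST00000180248 rose from 0.356 to 4.78 FPKM. Mrpl15 transcript ENSMUST00000156816 rose from the placeholder in each control to 6.22 FPKM. Whether isoform assignment shaped these 2 gene sums was not tested.

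Of 9781 genes tested with limma, these 6 and Zfp938 passed, 2 higher and 5 lower with PAMK. The log2 fold changes were -3.23 ± 0.0928 (SE) for Ranbp10 (limma adjusted p 0.00190), -2.80 ± 0.101 for Nfe2l1 (0.00315), -2.63 ± 0.154 for Ilvbl (0.0196), -3.41 ± 0.262 for Glrx (0.0460), 1.92 ± 0.102 for Rbm4 (0.0164) and 0.89 ± 0.0654 for Mrpl15 (0.0414). Zfp938 was listed at 1.39 to 1.82 FPKM in controls and at 0, 0 and 0.00817 FPKM with PAMK (log2 fold change -1.35 ± 0.0958, limma adjusted p 0.0414). Ranbp10 lies on chromosome 8 at 105768308 to 105827350, Nfe2l1 on chromosome 11 at 96817414 to 96829968, Ilvbl on chromosome 10 at 78574346 to 78584502 and Glrx on chromosome 13 at 75839868 to 75850154. Rbm4 lies on chromosome 19 at 4784293 to 4793901, Mrpl15 on chromosome 1 at 4773206 to 4785739 and Zfp938 on chromosome 10 at 82224850 to 82241273.

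Next by p, and not past the threshold, were 4 genes with higher values and 1 with lower values in the PAMK libraries. Clcn3, a chloride and proton exchanger, had 1.09 ± 0.246 FPKM in controls and 10.1 ± 3.00 with PAMK (limma adjusted p 0.0854). Cln6 had 0.591 ± 0.176 and 5.63 ± 1.40 FPKM (0.0854), Bms1, a ribosome assembly factor, 0.822 ± 0.301 and 6.01 ± 1.16 FPKM (0.0871), and Uck2, a uridine-cytidine kinase, 9.68 ± 2.68 and 43.0 ± 4.84 FPKM (0.134). Uck2 passed without control 1 (limma adjusted p 0.0380). It also passed with noncoding isoforms of the same gene name added (limma adjusted p 0.0297), where 9 genes passed. Bnip3, a mitophagy receptor and known hypoxia target, had 55.3 ± 1.74 FPKM in controls and 32.4 ± 2.51 with PAMK (0.0854). An unadjusted limma p under 0.05 was reached by 979 genes as deposited (72.9% higher with PAMK), by 942 after quantile normalization (45.2%) and by 1027 with equal medians (33.98%). Median gene FPKM was 4.03 to 4.09 in controls and 4.35 to 4.43 with PAMK, and making medians equal moved all fold changes by -0.10 on the log2 scale, so the balance of higher and lower genes is not given a direction. The median gene log2 fold change was 0.057 as deposited, -0.024 after quantile normalization and -0.040 with equal medians. Those 2 scalings thus put the typical gene slightly lower with PAMK. Ranbp10 and Nfe2l1 passed whichever library was left out, Rbm4 did not without PAMK 1 or PAMK 2, Ilvbl not without control 1, PAMK 1 or PAMK 2, Glrx only without PAMK 3, Zfp938 only without control 1 and Mrpl15 in none of the 6. Glrx also did not pass with pseudocounts of 0.1 and 0.5 (limma adjusted p 0.171 and 0.0834), without a filter (0.0751), without an eBayes trend (0.0550) or with robust eBayes (0.0592). Mrpl15 did not pass without an eBayes trend (0.0605) or with robust eBayes (0.0556), nor Zfp938 with robust eBayes (0.0553). Leaving out 1 library changed the count of 7 calls to 19 without control 1, 16 without control 2, 14 without control 3, 4 without PAMK 1, 11 without PAMK 2 and 15 without PAMK 3.

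**Figure D1:**
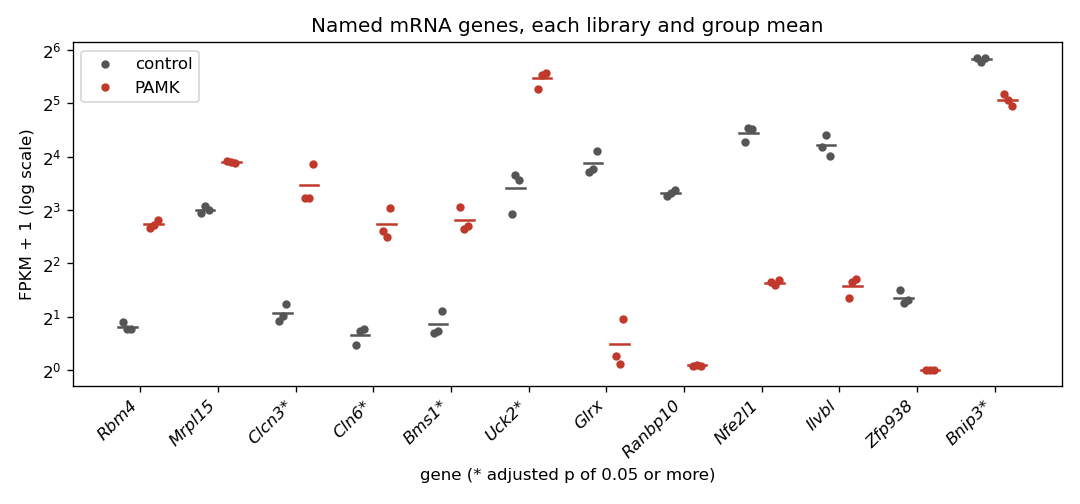
Points show FPKM + 1 in each total RNA library on a log scale for the 12 mRNA genes named by the rule, with controls in grey and PAMK in red, and short lines show group means (n = 3). Ranbp10 sat at 8.62 to 9.31 FPKM in the controls and at 0.0605 to 0.0773 FPKM with PAMK; a star marks a gene that did not pass.

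The lists asked whether genes of a shared function moved together. Of 22 lists tested, hypoxia and glycolysis genes were the 1 list that fell relative to other genes (camera p 0.000878, adjusted p 0.0193), with 14 of 22 members below 0 and 8 above, and the adjusted p was 0.575 with an estimated correlation, where no list passed. Fry, which asks whether a list moves to 1 side and compares it with no other genes, gave an adjusted p of 0.0999 for this list and passed 0 of the 22, with 7 at an unadjusted p under 0.05. Bnip3 was the 1 member to pass when adjusted over the list alone, and 0 members passed over all genes tested. With equal medians Bnip3 passed over all genes (limma adjusted p 0.0475), and as deposited its transcript ENSMUST00000106112 passed over all transcripts (0.0496). Slc2a1, the main glucose transporter of many cell lines, had 47.0 ± 3.47 FPKM in controls and 38.3 ± 2.87 with PAMK (log2 fold change -0.29 ± 0.0831), and P4ha2, a collagen prolyl hydroxylase, 6.99 ± 1.05 and 3.92 ± 1.25 FPKM (-0.73 ± 0.233). With equal medians 4 members passed adjusted over the list alone (Bnip3, Eno1, Slc2a1, and Pkm, whose log2 fold change of -0.0523 as deposited turned to 0.0134 with quantile normalization) and the list's adjusted p was 0.0144. That p was 0.142 after quantile normalization, 0.0882 without Bnip3, and 0.0862, 0.0851 and 0.0767 without control 1, control 3 and PAMK 2.

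**Figure D2:**
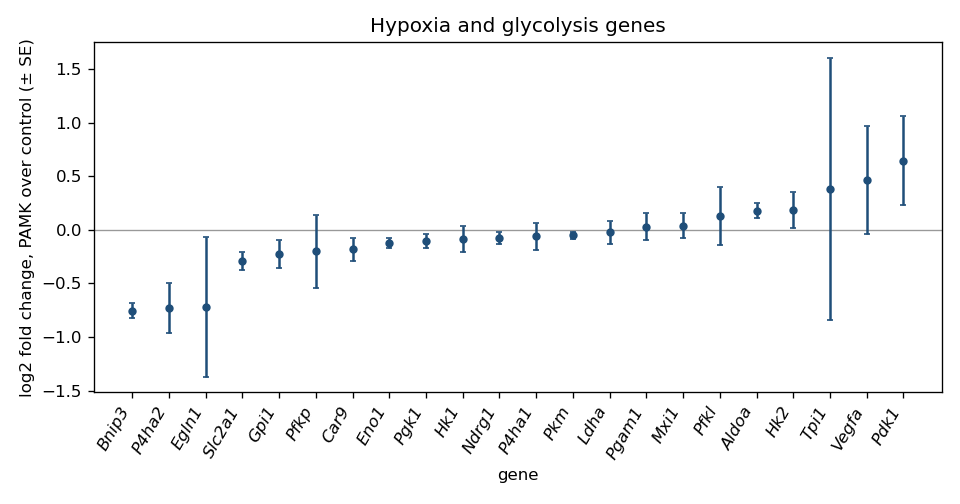
Points show the limma log2 fold change of PAMK over control for each of the 22 tested hypoxia and glycolysis genes, with bars for 1 SE (n = 3 per group). Bnip3 has the lowest value, -0.75, and 8 genes lie above 0.

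Unfolded protein and integrated stress response genes did not pass as a list (camera p 0.00802, adjusted p 0.0882; adjusted p 0.575 with an estimated correlation). Adjusted over the list alone 4 of 25 members passed, against 0 over all genes tested, 0 of 25 after the medians were made equal and the same 4 after quantile normalization. They were Mthfd2 and Shmt2, enzymes of mitochondrial folate metabolism, Slc3a2, an amino acid transporter subunit, and Sdf2l1, a chaperone partner of the endoplasmic reticulum. Shmt2 had 61.4 ± 2.11 FPKM in controls and 76.7 ± 5.0995 with PAMK, and Mthfd2 24.6 ± 1.29 and 30.6 ± 0.596 FPKM.

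Cell division genes were examined because the series design speaks of a dose that promoted proliferation. Of 43 G2/M genes 0 passed over all genes tested and 0 adjusted over the list alone (camera adjusted p 0.321). Their log2 fold changes lay above 0 in 32 and below 0 in 11. The list's camera p was 0.0235 with equal medians (adjusted p 0.258) and 0.00925 after quantile normalization (0.102). No list passed after that normalization. Its smallest camera p were those of ribosomal protein (0.00483) and G2/M genes, ahead of hypoxia and glycolysis genes (0.0222). Mki67, a marker of cycling cells, had 6.85 ± 1.35 FPKM in controls and 15.03 ± 4.97 with PAMK (limma adjusted p 0.392). Of 39 S phase genes 0 passed either way (camera adjusted p 0.687). Pcna, the replication clamp, had 238.5 ± 0.288 and 218.9 ± 8.44 FPKM (limma adjusted p 0.438), and Cdc45, a helicase component, 16.99 ± 0.629 and 9.96 ± 2.11 FPKM. Of 17 G1 cyclins and CDK inhibitors 0 passed either way (camera adjusted p 0.687). Ccnd1 had 24.8 ± 0.969 and 27.004 ± 0.0801 FPKM (limma adjusted p 0.512) and Cdkn1a 69.7 ± 13.2 and 63.6 ± 11.2 FPKM (0.843). Myc had 13.8 ± 0.267 FPKM in controls and 17.2 ± 2.53 with PAMK (0.490). Of 26 MYC and ribosome biogenesis genes 3 passed adjusted over the list alone, against 0 over all genes tested (camera adjusted p 0.538). These were Dkc1 (16.8 ± 0.976 and 24.97 ± 1.24 FPKM), Bop1 (42.0 ± 2.22 and 52.8 ± 2.97 FPKM) and the transferrin receptor gene Tfrc (188.7 ± 2.42 and 167.9 ± 4.55 FPKM); Bop1 no longer passed with equal medians.

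Adjusted over the list alone, fibroblast markers had 2 of 8 members past the threshold, Col1a1 (34.3 ± 5.20 FPKM in controls, 51.8 ± 5.15 with PAMK) and S100a4 (311.5 ± 12.9 and 369.4 ± 20.6 FPKM). Heat shock genes had Hspe1 of 11, NRF2 targets Hmox1 of 16, MHC class I presentation genes B2m of 13, apoptosis genes Bak1 of 19 and haematopoietic markers Cd68 of 2 tested members. Each of these 6 lists had 0 members past the threshold over all genes tested, and with equal medians 0 of the 2 fibroblast genes and neither Hspe1, Hmox1, B2m nor Bak1 passed, while Txnrd1, an NRF2 target with lower values, did; after quantile normalization B2m passed. Camera adjusted p was 0.321 for fibroblast markers, 0.444 for heat shock genes, 0.321 for NRF2 targets, 0.827 for MHC class I genes and 0.767 for apoptosis genes. Adjusted over the list alone and over all genes tested, 0 members passed among thymocyte support factors (10 tested, camera adjusted p 0.505), ribosomal protein genes (45, 0.321), replication-dependent histone genes (61, 0.673), NF-kB targets (19, 0.845), interferon-stimulated genes (22, 0.482), TLR pathway components (17, 0.403), immediate early genes (27, 0.434), p53 targets (20, 0.484), cholesterol synthesis genes (21, 0.482), extracellular matrix and TGF-beta genes (25, 0.321) and Wnt pathway genes (9, 0.321). With equal medians Rplp0 and Cxcl5 passed over the ribosomal protein and NF-kB lists alone, both with lower values, and after quantile normalization they did so with Rpl28 and Rps15, which had higher values. Ribosomal protein and histone genes have near-identical copies, so their values are uncertain. Tlr4, a Toll-like receptor gene, varied from 1.41 to 7.97 FPKM in controls and from 1.36 to 7.78 with PAMK.

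Of 22 medullary markers 1 was tested (Relb) and of 10 cortical markers 3 (Ctsl, Ly75 and Ccl25), with 0 past the threshold over all genes tested or adjusted over the list alone. Ctsl, a lysosomal protease, had 31.2 ± 6.57 FPKM in controls and 35.5 ± 4.12 with PAMK, Ly75 1.99 ± 0.0908 and 1.71 ± 0.702, Ccl25 2.24 ± 0.248 and 2.30 ± 0.719, and Relb 0.513 ± 0.0123 and 2.85 ± 2.54 FPKM. Krt5, Epcam and Aire were listed at 0 in all 6 libraries, Krt18 at no more than 0.0435 FPKM, Il7 at no more than 0.0153 FPKM, and Krt8 between 0.151 and 0.280 FPKM. Vim, a mesenchymal intermediate filament gene, was between 92.5 and 253.0 FPKM. Of 8 endothelial markers 0 were tested. All 13 mitochondrially encoded genes stayed below the filter, although every cell uses them, so for these genes a low listed value is not an absence of expression. That does not bear on the nuclear markers above, whose low values may be real. Whether the cells are epithelial as labelled was not tested.

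At the level of single transcripts 30 of 14729 passed in limma, 18 higher and 12 lower with PAMK, with 1101 at an unadjusted p under 0.05. Of the 30, 13 belonged to genes whose summed value had an unadjusted p of 0.05 or more. Abi1 transcript ENSMUST00000114544 was listed at the placeholder in the controls and averaged 13.4 FPKM with PAMK, while the gene sum had a log2 fold change of 0.28 ± 0.248. Vps28 transcript ENSMUST00000229019 likewise averaged 11.9 FPKM with PAMK, with 0.07 ± 0.0687 for the gene sum. These genes were chosen after their values were seen. Leaving out 1 library gave 22 (without PAMK 2) to 62 (without control 3) calls, with more than 1.5 times the count also without control 1 (47), PAMK 1 (54) and PAMK 3 (48), and without a filter on low values the count was 18. Of the 30 calls 14, 11 and 17 were made again without control 1, 2 and 3. Without PAMK 1, 2 and 3 it was 17, 9 and 17 of them.

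Of 23670 lncRNA transcripts 9 passed in limma, 6 higher and 3 lower with PAMK, with 1365 at an unadjusted p under 0.05. MSTRG.16071.1, an assembled transcript within the Cds2 locus on chromosome 2 at 132290025 to 132290373, fell: it was between 11.8 and 14.9 FPKM in the controls and at the placeholder in all 3 PAMK libraries (log2 fold change -7.03 ± 0.208, limma adjusted p 0.000434). Noncoding transcripts of Pfas (ENSMUST00000172915, 2.35 ± 0.152 to 0.0491 ± 0.0163 FPKM) and Idh3a (ENSMUST00000213729, 1.32 ± 0.198 to 0.0243 ± 0.00476 FPKM) also fell. A noncoding transcript of Phip (ENSMUST00000188868) rose from 0.0309 ± 0.0113 to 7.46 ± 1.45 FPKM, and 1 of Casc4 (ENSMUST00000135416) rose to 2.13 ± 0.393 FPKM. MSTRG.10222.9 in Lncppara rose to 1.40 ± 0.0915 FPKM, and MSTRG.24042.1 rose to 1.07 ± 0.225 FPKM from the placeholder in each control.

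Noncoding transcripts of Aaas (ENSMUST00000230710) and Ankle2 (ENSMUST00000196865) rose from the placeholder in each control to 2.14 ± 0.481 and 2.33 ± 0.936 FPKM. The coding Ankle2 transcript ENSMUST00000031474 fell from 8.49 to 0.00262 FPKM, while the sum of coding Ankle2 transcripts had a log2 fold change of -1.05 ± 0.824 (limma p 0.254). Of the 9 calls 7 carried the name of a gene in the mRNA table, as did 18294 of the 23670 tested. Summed by gene name, 0 of 22 abundant annotated lncRNAs, 0 of 17 snoRNA hosts and 0 of 8 miRNA hosts passed over all lncRNA genes tested in limma or adjusted over the list alone, with 1, 0 and 0 at an unadjusted p under 0.05. Malat1 was between 9.93 and 403.1 FPKM in controls and between 17.4 and 392.6 with PAMK, and Neat1 had 4.14 ± 0.425 and 5.16 ± 2.83 FPKM. A pseudocount of 1 left 3 calls (MSTRG.16071.1, Phip and Pfas) and a minimum mean of 0.5 FPKM left 2 (MSTRG.16071.1 and Phip), and leaving out 1 library gave 2 (without control 3) to 21 (without PAMK 1), with 14 without control 2. The calls of MSTRG.16071.1 and Phip held whichever library was left out, those of Idh3a and MSTRG.24042.1 in none of the 6 (limma adjusted p 0.0636 to 0.105 and 0.0758 to 0.139), that of Ankle2 only without PAMK 2 and that of MSTRG.10222.9 only without control 1. Pfas lost its call without control 2 or 3, Aaas without control 3, PAMK 1 or PAMK 2, and Casc4 without control 3 or any 1 PAMK library. Without a filter Idh3a, MSTRG.24042.1 and Ankle2 did not pass (0.0688, 0.0688 and 0.106), nor Ankle2 with equal medians (0.0511), nor Casc4, MSTRG.10222.9 and MSTRG.24042.1 with a pseudocount of 0.01.

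In the small RNA comparison 0 of 479 sequences passed in limma, with 75 at an unadjusted p under 0.05. A suffix such as _R+1 is the deposited mark for a length variant. The smallest p among higher values were those of miR-23a-3p_R+1 (156899 ± 8910 normalized counts in controls and 209972 ± 6636 with PAMK), miR-19b-3p (300.8 ± 65.1 and 779.9 ± 250.2) and miR-145a-5p (14299 ± 2493 and 25850 ± 4348), each with a limma adjusted p of 0.164. Among lower values they were those of the hairpin arm mir-690-p3 (272.9 ± 46.5 and 145.5 ± 30.8), miR-210-5p, from a hairpin known to be induced by hypoxia (994.3 ± 92.9 and 691.5 ± 46.7), and PC-3p-8409_312 (74.02 ± 11.1 and 33.6 ± 11.6). miR-21a-5p_R+1 had 131190 ± 9254 and 153417 ± 29923 normalized counts (limma adjusted p 0.450).

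Without PAMK 1, 138 of 480 sequences passed in limma, 68 higher and 70 lower, and leaving out any other library gave 0. Sequences called higher had a median length of 24 nt and those called lower 21 nt, against 22 nt for all tested. Across all tested sequences the log2 fold change with all libraries correlated with sequence length (Spearman rho 0.69 across sequences, which are not independent replicates). The share of normalized counts in sequences of at least 23 nt was 18.6% to 20.96% in controls, 19.1% in PAMK 1, 27.6% in PAMK 2 and 24.6% in PAMK 3. miR-23a-3p_R+1, miR-19b-3p and miR-145a-5p passed in limma once each library's length trend was removed (adjusted p 0.0324 for each), an alternative chosen after the data were seen.

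**Figure D3:**
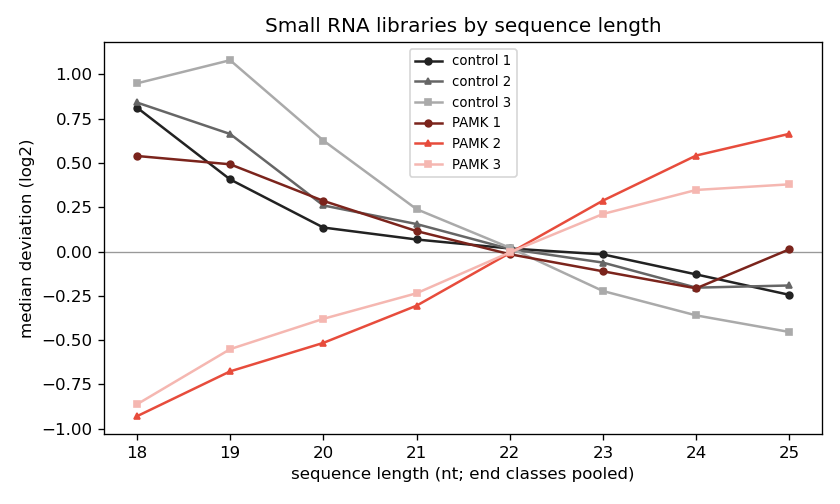
Lines show, for each of the 6 small RNA libraries, the median deviation of log2 values from the mean over libraries against sequence length in nt, with lengths of 18 nt or less and of 25 nt or more pooled. At 24 nt PAMK 2 and PAMK 3 lie at 0.54 and 0.35, and PAMK 1 lies at -0.21 near the controls.

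By family, and adjusted over the list alone, sequences past the threshold numbered 2 of 19 in the miR-17/92 clusters (miR-19a-3p and miR-19b-3p), 2 of 7 in the miR-29 family (miR-29a-5p_R+3 and miR-29b-1-5p_R+2), 2 of 7 in the miR-181 family, 2 of 10 in the miR-23/24/27 clusters (miR-23a-3p_R+1 and miR-23b-3p_R+3), 1 of 10 endothelial and mesenchymal miRNAs (miR-145a-5p), 1 of 15 inflammation-associated miRNAs (miR-221-5p) and 1 of 3 epithelial miRNAs (miR-200b-3p_R+1). None of these passed over all sequences tested in limma, where the count was 0. The let-7 (20 tested), miR-34 (7), miR-15/16 (12), miR-30 (11), miR-99/100 and miR-125 (11), haematopoietic (3) and muscle and liver (2) lists had 0 adjusted over the list alone. All 11 sequences past the threshold had higher values with PAMK. Several of them are length variants, and sequences of 24 nt had median deviations of 0.54 in PAMK 2, 0.35 in PAMK 3 and -0.21 in PAMK 1. Removing the length trend turned miR-181a-5p_R+2 to a log2 fold change of -0.10, and with PAMK 1 also left out miR-23b-3p_R+3 turned to -0.25. How many of the 11 would pass over their lists without the length trend was not tested. miR-200b-3p_R+1 leaned on PAMK 1, with 115.7 normalized counts there and 24.6 and 27.96 in PAMK 2 and PAMK 3, and its log2 fold change was 1.83 with and 1.13 without that library. The epithelial list summed to 110.3 ± 21.6 normalized counts in controls and 213.4 ± 64.6 with PAMK, against 66644 ± 2566 and 75090 ± 2956 for the endothelial and mesenchymal list.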

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

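The alternatives that removed the length trend, left out genes by their range, added noncoding isoforms, summed lncRNAs by gene name or used an unadjusted p alone for mRNA and lncRNA were chosen after the data were seen; the others were set before the data were examined. The authors' own calls were not run as an alternative because the tables used here hold none. Among 82 named genes and RNAs there were 1263 alternative values, of which 1115 kept their direction and side of the threshold. Of the others 96 lost the threshold, 32 gained it and 20 reversed. Most of the 82 had not passed as planned, so for them keeping the side of the threshold was likely beforehand. The 96 losses could come only from the 7 mRNA genes and 9 lncRNA transcripts that had passed. The share that kept both therefore does not measure how stable the calls are.

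For mRNA genes the count of 7 became 4 with robust eBayes, 179 at an unadjusted p under 0.05 with a log2 fold change of at least 1, and 979 at an unadjusted p under 0.05 alone. Limited to genes whose 6 log2 values span at most 0.5, 1, 1.5, 2 and 3 it was 18, 2, 2, 0 (968 at an unadjusted p under 0.05 in limma) and 4. That span includes the difference between groups, so a narrow limit leaves out strongly changed genes. Of the 7 calls made as planned, 0, 1, 2, 0 and 4 were among these, so the 18 were all other genes. For mRNA transcripts 30 became 18 without a filter, 376 at an unadjusted p under 0.05 with a log2 fold change of at least 1, and 1101 at an unadjusted p alone. For lncRNAs 9 became 3 with a pseudocount of 1, 2 with a mean of at least 0.5, 2 summed by gene name, 805 at an unadjusted p under 0.05 with a log2 fold change of at least 1, and 1365 at an unadjusted p alone. For miRNAs 0 became 75 at an unadjusted p under 0.05, 3 with the length trend removed and 36 with PAMK 1 also left out. For gene lists 1 became 0 with an estimated correlation, with quantile normalization and with fry (7 at an unadjusted p under 0.05), which makes no comparison with other genes. The cause of these changes was not tested.

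Leaving out each library gave 4 to 19 mRNA genes, 22 to 62 transcripts, 2 to 21 lncRNAs, 0 to 138 miRNAs and 0 to 1 gene lists. With the replicate number as a block, limma called 0 genes, 0 transcripts, 0 lncRNAs and 0 miRNAs (707, 833, 1175 and 62 at an unadjusted p under 0.05), and camera called 1 list. Over all rows the numbers showed no pairing: same-numbered libraries deviated together with correlations of -0.02, 0.01 and 0.00 over genes and -0.10, 0.08 and 0.02 over miRNAs. Such correlations cannot exclude a shared batch that moves few genes. Malat1 had 403.1, 9.93 and 298.35 FPKM in controls 1, 2 and 3. In PAMK 1, 2 and 3 it had 392.6, 17.4 and 349.0 FPKM, in the same order. Tlr4 did not keep its order (3.41, 7.97 and 1.41 against 7.26, 1.36 and 7.78 FPKM). Whether the numbers pair the samples thus stays open.

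Values that reversed were those of Cdkn1a (-0.28 without control 3 to 0.0250 without PAMK 3), Tlr4 (-0.18 without control 3 to 0.90 without PAMK 2, with -0.00643 without PAMK 1 and -0.0506 without PAMK 3), miR-21a-5p_R+1 (-0.0197 with the length trend removed, -0.000752 with PAMK 1 also left out), miR-181a-5p_R+2 (-0.10 and -0.12), and, with the trend removed and PAMK 1 left out, miR-23b-3p_R+3 (-0.25) and PC-3p-8409_312 (0.11). Others were Ly75 (-0.32 without PAMK 1 to 0.0566 without PAMK 3), Pkm (0.0134 with quantile normalization) and Ccl25, whose value lay near 0 (0.00175): -0.0101 and -0.00290 with pseudocounts of 0.1 and 0.5, -0.0947 with quantile normalization, -0.0955 with equal medians, -0.18 with noncoding isoforms added, and -0.14 without PAMK 2 to 0.18 without PAMK 1, with -0.0632 without control 3 and -0.0352 without PAMK 3. None of these had passed over all genes or sequences tested. The unknown depth of the total RNA libraries leaves the counting error of low FPKM open.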

Other observations

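The tests of sequence length, of the PAMK 1 label, of genes low in a whole group, of noncoding isoforms, of miR-210 and of culture time were chosen after the results were seen, as were the splits except that for gene lists; the test without Bnip3 was set before its value was seen. The locus listed as CT010467, which is known to hold ribosomal RNA sequence, summed to between 19967 and 30540 FPKM in control libraries and between 14594 and 19034 FPKM with PAMK. The groups thus differed in this locus as well as in median gene FPKM and in mRNA transcripts at the placeholder, and which of the gene and list changes move with these was not tested beyond the scalings. Estimated reads were fewest in the small RNA library PAMK 1, at 4104360. In that library miR-200a-3p_R+1 was 63.7 and miR-200b-3p_R+1 115.7 normalized counts, against at most 6.72 and 28.0 in the other 5 libraries.

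Small RNA differences ran with sequence length, and a length bias between libraries is a candidate explanation. Libraries of the same group also differed along length, with a rank correlation of -0.48 for control 3 against the other controls and -0.55 for PAMK 1 against the other PAMK libraries (the smaller of these in size, 0.482, was the test value), which the treatment label does not account for. Without PAMK 1 there were 138 calls before and 36 after removing the length trend, 26 of them in both and 10 only after, while the other 9 ways of dividing those 5 libraries gave 0 each time, so whether length is the whole cause stays open. PAMK 1 stood apart from both groups: its highest correlation with a control was 0.955, below the lowest between controls, 0.981, and with the other PAMK libraries it was 0.951 to 0.955, against 0.986 between PAMK 2 and PAMK 3. A wrong label for PAMK 1 therefore stays open, the more so as the protocol speaks of more small RNA libraries than the 6 used here, and so does an effect of PAMK on small RNA length.

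Several called genes were near 0 in every library of a group, which random failures of isoform assignment could produce. Among 5728 genes that reached 5 FPKM, 26 were at under 0.25 of their highest value in all controls and only there, and 17 in all PAMK libraries, against a median of 11 (range 7 to 31) for the 18 other sets of 3 libraries. At least 26 were low in 1 of those sets and at least 17 in 3, and the groups together held 43, against at most 42 for another split, so random failures and an effect of PAMK on single genes both stay open. An equal move of FPKM to noncoding isoforms of the same name is argued against for Glrx, Ilvbl, Mrpl15, Ranbp10 and Rbm4, where these offset at most 0.0156 of the change in FPKM (0.0744 when 2 SE are added). FPKM is divided by transcript length, so reads that moved to a longer isoform would show as a smaller offset. Transcripts without a gene name were not counted. With the noncoding isoforms of its name added Glrx had a log2 fold change of -2.18 ± 0.140 in place of -3.41 ± 0.262. Nfe2l1 and Zfp938 have no such isoforms and were not tested.

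Hypoxia and glycolysis genes lay lower with PAMK relative to other genes with camera's preset correlation, but not past the threshold with an estimated correlation (adjusted p 0.575), and a weaker hypoxia response is a candidate explanation. Without Bnip3 camera's p was 0.00692, under the bound of 0.01 set beforehand, but that bound was the wrong one because the call rests on the adjusted p, which was 0.0882. The call thus ended without Bnip3, with a mean log2 fold change of -0.04 ± 0.0711 (SE over 21 members) in place of -0.07 ± 0.0752 over 22, and whether this 1 gene carries the list stays open. miR-210-3p had a log2 fold change of -0.29 ± 0.157 (limma adjusted p 0.357) and miR-210-5p -0.52 ± 0.122 (0.164), neither past the threshold. Without PAMK 1 both passed (-0.46 ± 0.0909, 0.00614, and -0.57 ± 0.112, 0.00610), but so did 138 of the 480 sequences tested. The answer thus rests on the library that stands apart and stays open. Culture time cannot be told apart from PAMK, because the control time in the series design is 6 h shorter and no untreated culture of the longer time is among the groups.

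The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. For mRNA genes 6 of the 10 splits gave at least the real 7 calls (highest other 17), for transcripts 1 gave at least 30 (highest other 25), for lncRNAs 6 gave at least 9 (highest other 16), for miRNAs 10 gave at least 0 (highest other 0, limma, with 75 at an unadjusted p under 0.05 in the real split and up to 102 in the others) and for gene lists 4 gave at least 1 (highest other 2). The hypoxia list had a camera p of 0.000878 in the real split and 0.0482 to 0.930 in the others, and with the length trend removed the real split gave 3 miRNAs and the others 0 (limma, 48 and 3 to 52 at an unadjusted p under 0.05). At an unadjusted p under 0.05 the real split gave 979 mRNA genes and the others 327 to 421, for transcripts 1101 and 533 to 607, and for lncRNAs 1365 and 870 to 1415. Among genes with spans of at most 0.5, 1, 1.5, 2 and 3, the real split gave 18, 2, 2, 0 and 4 calls. The highest other split gave 0, 0, 2, 4 and 12. These gene splits used values as deposited, where making medians equal moved gene fold changes by -0.10 on the log2 scale. A shift of a whole group can by itself give calls among genes with a narrow span. Whether it gave the 18 was not tested.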
